A study of Mus musculus with 12 samples.

How the data were processed

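Small RNA libraries from 12 samples, 6 model and 6 Keluoxin, were used, 1 processed table per sample. Per the labels' protocols, they were made from 1 µg of total RNA with the NEBNext small RNA kit and sequenced on an Illumina NextSeq 500 after selection of inserts of 15 to 35 nt. The source label names the retina, whereas the extraction text speaks of an exosome pellet; the tissue is taken here from the source label. The strain label gave the db/db genotype and a KsJ background; the number before BL in it rises by 1 from sample to sample and was not used. The labels do not say that the 6 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

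The submitters' processing notes name bcl2fastq, cutadapt, Bowtie and Novoalign, without versions or roles. The genome build and miRBase release behind the precursors are not given in the sources used here. Each deposited table lists distinct read sequences with their read counts, the precursors they align to, and the positions and number of differing, inserted or deleted bases, per the file headers. The deposited counts are whole reads, not normalized, of sequences with at least 2 reads and 15 to 51 nt long. Where a sequence matches several precursors, the authors divided its count by their number and rounded it, within 0.5 of a read in 100% of rows, and the undivided number was kept in the tag name. The other deposited values, lengths and positions on the precursor, have no normalization per the file headers, and positions are counted with 5 added.

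Undivided reads were counted once per mature arm, by the side of the middle of the precursor on which the read lies, and reads shared by several precursors were shared equally or counted under a joint name. This gave 2143 arms, 717 of them from precursors predicted by the submitters; 997 annotated and 535 predicted precursors were seen. Of the reads, 2.53% fell on several miRNAs and 32.3% on several precursors. Joint names were given to copies of annotated precursors only, so copies of predicted ones stayed separate arms that share reads. Names of predicted precursors are not given here; such arms are named by their most frequent read. Precursors were matched by sequence to GENCODE M21 transcripts of the GRCm38 assembly, and coordinates come from that match alone: 991 of 997 annotated and 88 of 535 predicted precursors matched. Reads were also matched to ribosomal, mitochondrial transfer and other small RNA transcripts over at least 15 nt. Transfer RNAs of the nuclear genome were not among these classes.

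Levels were compared with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filter on low counts and its quasi-likelihood test on 811 arms, and Benjamini-Hochberg adjustment at 0.05. Normalized CPM are counts over TMM-scaled library sizes. The biological coefficient of variation was 0.480. On simulated counts for this comparison, 811 arms with 67 changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, the same fit recovered 10.4%, 47.8% and 75.8%, with 1 unchanged arm called. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and beside it with an estimated correlation and fry, for one direction and mixed; lists needed at least 3 tested members. Arm ratios were tested with limma on log2 of 5p plus 0.5 over 3p plus 0.5 reads (at least 10 reads on each arm in 6 libraries), read length and start shifts with limma on arms with at least 50 reads in every library. In a simulation with 36 of the 147 precursors shifted by 1 log2 unit, 55.6% were recovered and no unchanged one was called. Measures per library were compared by exact two-sided permutation tests over 924 assignments, whose smallest p is 0.00217. Adjustment was over the 7 measures of make-up. Read classes, tRNA genes, short sequences, kinds of mismatch and other sets were each adjusted within their own set. Pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and BLAST+ 2.17.0 were used in Python 3.11.15.

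Arms to be named were fixed before the data were examined: of the called arms, the 10 higher and 10 lower with the largest change; the 10 most abundant; the 3 most abundant of each list; and the 3 smallest p of the arm, length and start tests. Since 9 of the 10 higher and 8 of the 10 lower were predicted precursors, the annotated arms with the largest change or smallest p were added after the data were seen, as were miR-125b-5p, miR-99a-3p, miR-374b-5p, miR-136-3p, miR-30b-5p, miR-29a-3p and other arms named for their calls, and all reads of other RNA classes. The 18 lists held the sensory cluster, neuronal and retinal, pigment epithelium and ciliary, epithelial, endothelial, mural, erythroid, leukocyte, muscle, liver, gut and pancreas, inflammation, miR-34, VEGF and retinopathy, let-7, miR-29, miR-30, miR-17 to miR-92 and Dlk1-Dio3 miRNAs. The Dlk1-Dio3 list names 56 precursors, whose arms were tested separately.

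No library pair was a copy: the smallest chi-square per degree of freedom between libraries of a group was 74.2, and Spearman correlations within groups ran from 0.843 to 0.974. Alternatives included DESeq2 1.42.0, limma-voom, other scalings, filters on low counts, read selections, the replicate number as a block and leaving out each library in turn. After the data were seen, fits with annotated precursors only, without model replicate 1 and Keluoxin replicate 4, and with the share of predicted precursors as a covariate were added. PCR reads without molecular identifiers are not independent molecules.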

Results

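Small RNAs were sequenced from the retina of db/db mice, which lack a working leptin receptor and become obese and diabetic. The labels give 6 libraries called model, taken here as db/db mice not given Keluoxin, and 6 treated with Keluoxin, a Chinese herbal capsule. The comparison asks how the treatment changed the retinal miRNA profile. The libraries held between 1933375 counted reads (Keluoxin replicate 5) and 7892147 (model replicate 3), and 62878432 in all. The difference in depth between the groups did not pass the test (5801480 ± 1540800 reads in model and 4678260 ± 1481280 in Keluoxin, SD, n = 6 each, exact permutation test, adjusted p = 0.409). No non-diabetic mice were analysed here, so every value compares Keluoxin with model retina of db/db mice.

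The most abundant miRNAs were those of a neural retina. In the model libraries miR-182-5p stood at 183100 ± 12550 CPM (counts scaled to library size, SD, n = 6), miR-183-5p at 157900 ± 12020, miR-9-5p at 69250 ± 3578, miR-30a-5p at 50510 ± 21950, miR-124-3p at 46620 ± 6760, miR-96-5p at 42890 ± 3801 and miR-181a-5p at 39150 ± 2072. miR-182, miR-183 and miR-96 are made from one cluster that is highly expressed in photoreceptors, and miR-124 and miR-9 are neuronal miRNAs. Of the 10 most abundant arms, which also include miR-26a-5p, let-7g-5p and miR-30d-5p, only miR-182-5p passed the test between the groups.

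Of the annotated arms that were lower in Keluoxin, the most abundant was miR-182-5p. It fell to 120000 ± 28350 CPM (log2 fold change −0.61, SE 0.15, edgeR adjusted p = 0.0210). Its level was below all model libraries in each of the 6 Keluoxin libraries. miR-126a-3p, an endothelial miRNA, fell from 1651 ± 181 to 1064 ± 130 CPM (−0.63, SE 0.11, adjusted p = 0.00515). miR-744-5p had the smallest p among annotated arms and fell from 362.6 ± 54.3 to 188.2 ± 26.3 CPM (−0.95, SE 0.13, adjusted p = 0.00244). miR-125b-5p, 8433 ± 1255 CPM in model, stood at 5832 ± 597 in Keluoxin, and miR-378a-3p, 2391 ± 490 CPM, at 1426 ± 188. miR-330-5p, miR-379-5p, miR-674-3p, miR-183-3p and miR-203-3p fell by 0.68, 0.75, 0.85, 0.72 and 0.82 on the log2 scale. The islet miRNA miR-375-3p fell by 0.39. All 10 of these arms, and miR-182-5p, passed when any 1 library was left out.

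The precursors lie at known miRNA genes in the GRCm38 assembly. mir-182, mir-96 and mir-183 are on the minus strand of chromosome 6 at 30165918 to 30165992, 30169446 to 30169551 and 30169668 to 30169737, outside other annotated genes. mir-126a is on chromosome 2 at 26591357 to 26591429, where it overlaps an exon of Egfl7. mir-744 lies in an intron of Map2k4 on chromosome 11 at 65734733 to 65734832, and mir-378a in an intron of Ppargc1b on chromosome 18 at 61397835 to 61397900. mir-451a is on chromosome 11 at 78073170 to 78073241, outside other annotated genes.

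With the main scaling, fewer annotated miRNAs were higher than lower in Keluoxin; this order turned when libraries were scaled to total reads. Among annotated arms past the threshold, the largest rise was that of miR-451a-5p, an erythroid miRNA, from 30.97 ± 8.30 to 256.3 ± 238.3 CPM (log2 fold change 3.05, SE 0.69, edgeR adjusted p = 0.0155). This rise was uneven: Keluoxin replicates 3, 4, 5 and 6 held 322.2, 358.7, 649.7 and 147.3 CPM, and replicates 1 and 2 held 24.87 and 34.97, within the model range of 20.84 to 43.44. miR-374b-5p rose from 230.7 ± 33.0 to 404.2 ± 100.8 CPM, miR-136-3p from 357.2 ± 63.1 to 552.2 ± 113.2, miR-30b-5p from 4177 ± 450 to 5643 ± 464 and miR-99a-3p from 2.205 ± 0.466 to 4.570 ± 0.844, all past the threshold and with every library left out in turn. The liver miRNA miR-122-5p rose from 2.519 ± 1.338 to 15.37 ± 14.94 CPM (log2 fold change 2.56, SE 0.65, adjusted p = 0.0219); without model replicate 4 the log2 fold change was 2.44 and the call was lost (adjusted p = 0.0552). miR-29a-3p and miR-29c-3p, which target collagen mRNAs, rose by 0.31 and 0.54, and each lost the call in 5 of the 12 fits with 1 library left out. miR-3473a-3p, miR-3473e-5p, miR-3473f-3p, miR-1195-3p and miR-690-3p also rose. Their most frequent reads carry B1, B2 or Gm22369-like sequences, and of these arms only miR-1195-3p passed in every fit with 1 library left out.

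**Figure D1:**
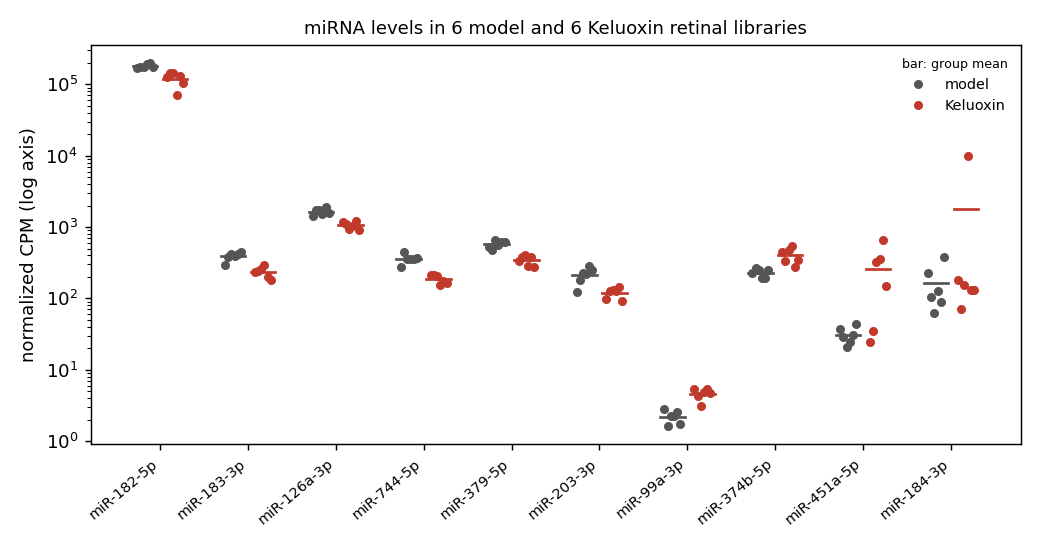
Normalized CPM of 10 miRNA arms (log axis) in each of 6 model and 6 Keluoxin libraries; points are libraries and short lines arithmetic group means. miR-182-5p, miR-126a-3p, miR-744-5p and miR-379-5p lie lower in every Keluoxin library than in all model libraries, miR-451a-5p is raised in 4 of 6 Keluoxin libraries, and miR-184-3p reaches 9994 CPM in Keluoxin replicate 4.

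In all, 140 of 811 tested arms differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 75 higher and 65 lower in Keluoxin. Of 511 annotated arms, 21 were higher and 49 lower. Of 300 arms of precursors predicted by the submitters, 54 were higher and 16 lower. Copies of predicted precursors that share reads count here as separate arms. A pair of the lower ones had equal values, 66.26 ± 35.97 CPM in model and 21.18 ± 9.755 in Keluoxin. The direction of the annotated arms as a class depended on the scaling. Scaled to total counted reads, 34 annotated arms were higher and 17 lower, and all arms split 89 to 26 (77.4% of 115 calls higher, against 53.6% of 140). Scaled by the upper quartile, 14 annotated arms were higher and 89 lower, and all arms split 72 to 110 (39.6% higher). These scalings moved the median log2 fold change of all arms from 0.03 to 0.22 and −0.23. When only annotated precursors entered the fit, the split was 38 to 37. Of the 70 annotated called arms, 27 were called under all 4 scalings (TMM, RLE, upper quartile and total reads), and 32 in every fit that left out 1 library. The count was 244 without model replicate 1, 72 without model replicate 4, 86 without model replicate 3 and 93 without model replicate 5, and 228 without model replicate 1 and Keluoxin replicate 4, a pair left out after the data were seen. With DESeq2 and its own filter it was 236 of 1344 arms. It was 28 with the share of predicted precursors as a covariate, a fit added after the data were seen. Model replicate 1 lay on the Keluoxin side of the first principal component, which held 52.6% of the variance.

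Of 18 lists of miRNAs fixed before the data were examined, only the imprinted Dlk1-Dio3 cluster passed the camera test with a preset correlation of 0.01. Of its 66 tested arms, miR-136-3p was higher and 12 were lower, among them miR-379-5p, miR-379-3p, miR-411-5p, miR-369-5p, miR-134-5p and miR-770-3p. Adjusted over the list alone, 1 was higher and 14 lower. This test gave an adjusted p = 0.0171 for a lower level, which did not hold with an estimated correlation (adjusted p = 0.820). The median log2 fold change was −0.18, and 0.00 when scaled to total reads. The call was also lost without model replicate 3 (adjusted p = 0.261), without Keluoxin replicate 4 (adjusted p = 0.0606) and with annotated precursors only (adjusted p = 0.346). The fry test for one direction passed for 0 of the 18 lists. Its mixed form asks for a change of either sign without comparing the list with other arms, and was read after the data were seen. It passed for 7 (adjusted p of at most 0.0105): the Dlk1-Dio3, sensory, neuronal and retinal, endothelial, VEGF and retinopathy, miR-30, and liver, gut and pancreas lists.

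The other 17 lists did not pass the camera test (preset correlation, adjusted p from 0.254 to 0.984). In the sensory cluster of miR-183, miR-96 and miR-182, 2 of 6 arms fell, miR-182-5p and miR-183-3p, while miR-96-5p stood at 52220 ± 5855 CPM in Keluoxin against 42890 ± 3801 (edgeR adjusted p = 0.0539; list adjusted p = 0.254; adjusted over the list alone, 1 higher and 3 lower). Of 28 neuronal and retinal arms, miR-181c-5p rose and miR-129-5p, miR-129-1-3p, miR-125b-5p and miR-330-3p fell (list adjusted p = 0.269; adjusted over the list alone, 2 higher and 4 lower). The abundant neuronal arms miR-9-5p and miR-124-3p were at 58700 ± 13190 and 36960 ± 7978 CPM in Keluoxin and did not pass. Of the 8 endothelial arms, and of the 11 arms of a list on VEGF, angiogenesis and diabetic retinopathy, only miR-126a-3p fell (list adjusted p = 0.528 and 0.545; adjusted over the list alone, 1 lower in each). Of the miR-30 family, miR-30b-5p rose and miR-30e-3p fell among 8 (list adjusted p = 0.459; adjusted over the list alone, 1 higher and 3 lower). Of the miR-29 family, miR-29a-3p and miR-29c-3p rose among 6 (list adjusted p = 0.545; adjusted over the list alone, 2 higher). The let-7 family with 10 arms, the miR-17 to miR-92 clusters with 9, the inflammation list with 6 and the miR-34 list with 3 had no call, also adjusted over the list alone (list adjusted p = 0.466, 0.528, 0.545 and 0.984).

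The 6 arms of the pigment epithelium and ciliary body had none (list adjusted p = 0.856), with miR-204-5p at 7122 ± 695 CPM in model and 7398 ± 283 in Keluoxin, and the 5 leukocyte arms had none (list adjusted p = 0.984). Of 3 erythroid arms miR-451a-5p rose (list adjusted p = 0.459), and all 3 were higher adjusted over the list alone. The others, miR-486a-5p and miR-486b-5p, are not independent. Their precursors overlap on opposite strands of chromosome 8, and their levels were nearly equal (126.2 and 129.3 CPM in Keluoxin replicate 3). miR-486a-5p stood at 32.58 ± 2.63 CPM in model and 56.50 ± 37.18 in Keluoxin (edgeR adjusted p = 0.120). Of 8 arms of liver, gut and pancreas, miR-122-5p rose and miR-375-3p and miR-216b-5p fell (list adjusted p = 0.280; adjusted over the list alone, 1 higher and 4 lower). Of 6 epithelial arms miR-203-3p fell, of 10 arms of mural cells miR-24-1-5p fell, and of 5 muscle arms miR-133b-3p rose (list adjusted p = 0.459, 0.984 and 0.466). Adjusted over the list alone, these lists gave 1 lower, none and 1 higher. The miR-133b-3p call was lost in 10 of the 12 fits with 1 library left out, and its level was highest in Keluoxin replicate 4, at 18.8 CPM against 1.69 to 4.75 in the other 5 Keluoxin libraries. In that library 4 of the 5 muscle arms had their highest level, against 14.8% of all arms. For the liver, gut and pancreas list, the mean log2 fold change was 0.26 where the median was −0.27 and the test pointed lower; the median of the miR-34 list and the mean of the endothelial list also differed in sign from their tests.

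Reads of other RNA classes differed between the groups as well, and they lead part of the predicted arms. Reads of the mitochondrial serine tRNA gene mt-Ts2 (chromosome M, 11613 to 11671, plus strand) fell from 5902 ± 1642 to 1810 ± 949 RPM (reads scaled to all counted reads of the library), lower in all 6 Keluoxin libraries (exact permutation test, p = 0.00217, adjusted over 11 tRNA genes 0.0238). An arm led by AAGAAAGATTGCAAGA, a fragment of this tRNA, fell from 3956 ± 1597 to 1142 ± 529 CPM (log2 fold change −1.79, SE 0.33, edgeR adjusted p = 0.00796). An arm led by AGATTGCAAGAACTG, also of mt-Ts2, fell by 2.03. mt-Tf reads fell as well, from 46.4 ± 36.4 to 9.44 ± 6.14 RPM (exact permutation test, adjusted p = 0.0238), and they make up 90.8% of the reads of miR-6481-3p, which fell by 2.13 and turned to a value of 0.87 that did not pass when reads of 18 to 26 nt were used. mt-Te stood at 718.4 ± 258.3 against 339.4 ± 178.8 in model, and mt-Th at 919.9 ± 345.5 against 436.7 ± 232.6 (exact permutation test, adjusted p = 0.0595 each). Shares of RNA classes count reads whose whole sequence lies in an annotated transcript. Nuclear tRNA was not a class, so its fragments would count among reads that match none, unless they match another class. The share of mitochondrial tRNA fell from 0.825% ± 0.138 to 0.488% ± 0.187 (exact permutation test, adjusted p = 0.00722), and without mt-Ts2 it stood at 0.235% ± 0.076 and 0.307% ± 0.107 (exact permutation test, p = 0.182). The share of ribosomal RNA rose from 0.139% ± 0.089 to 0.321% ± 0.105 (adjusted p = 0.0379, exact permutation test), and the shares of small nuclear and nucleolar RNA did not pass (adjusted p = 0.342 and 0.699, exact permutation tests). The share matching annotated miRNA transcripts fell from 57.9% ± 2.1 to 49.3% ± 2.4, and the share matching none of these classes rose from 40.7% ± 1.8 to 49.2% ± 2.5 (exact permutation tests, adjusted p = 0.00722 each). Most of this restates a rise in mismatches, since a changed base leaves a read unmatched: unmatched reads with a mismatch to their precursor took 39.7% ± 1.5 and 47.1% ± 2.6, and those without one 1.04% ± 0.56 and 2.14% ± 0.50 (exact permutation tests, adjusted p = 0.00649 and 0.00866). Distinct sequences for each 1000 reads depend on depth, so they were compared at 1933375 reads per library, where they rose from 11.25 ± 0.81 to 13.64 ± 1.30 (exact permutation test, adjusted p = 0.0130; 6.89 ± 1.52 and 9.61 ± 2.31 over all reads).

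Reads of a few short sequences rose in Keluoxin. Here every read that holds the sequence was counted, also with other bases around it, so these values can exceed the class shares above. Those with TGGAGAGATGGCTC, from the 5′ part of the B2 short interspersed element, rose from 171 ± 196 to 836 ± 380 RPM (exact permutation test, adjusted p = 0.00649). Reads with TTAAAGGCTAGGCT, shared by annotated miRNA genes such as Gm22369, rose from 828 ± 1013 to 4206 ± 722 (adjusted p = 0.00433), and those with ACCGGGTGCTGTAGG of 5S ribosomal RNA from 7147 ± 5083 to 17120 ± 5123 (adjusted p = 0.00866). Reads with CTCTCCAGCCACC rose from 873 ± 629 to 2405 ± 571 (adjusted p = 0.00779), all by exact permutation tests. These 4 sequences lead 20 of the 54 predicted arms that were higher, 0 of the 16 that were lower and 8 of the 230 without a call; the sequences were chosen after the calls were seen. With variants, which share 10 bases in a row with a sequence or differ from it in 1, the numbers were 29, 0 and 17. Arms that share reads are counted separately in these numbers. Model replicate 1 held the most of each of the 4 among the model libraries, with 2870 RPM for TTAAAGGCTAGGCT, 560 for TGGAGAGATGGCTC, 15170 for ACCGGGTGCTGTAGG and 2009 for CTCTCCAGCCACC, against 419 ± 177, 93.0 ± 47.9, 5542 ± 3604 and 646 ± 328 over the other 5. It stood clearly apart only for the Gm22369-like and B2 sequences, where the next model library held 598 and 170 RPM. For the 5S sequence model replicate 6 held 11173, close to Keluoxin replicates 1 and 3 (11405 and 11312). For the last sequence model replicate 2 held 1148. Of the predicted arms, 64 of 300 took over 50% of their reads from tags that also match annotated precursors, so their values are uncertain.

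The predicted arms with the largest rises had few reads in model. An arm led by TTAGTTGGTGGAGCGAT had the largest fold, from 2.64 ± 3.72 to 65.6 ± 118.3 CPM (log2 fold change 4.69, SE 1.34, edgeR adjusted p = 0.0321), with 305.5 CPM in Keluoxin replicate 4, and lost the call in 6 of the 12 fits with 1 library left out. Arms led by ACCGGGTGCTGTGGGCC, TGGAGAGATGGCGCA, TGTAAACATCCCCTG and CTCTCCAGCCACATTTT rose by 3.72, 3.67, 3.25 and 3.14 (SE 0.95, 0.71, 0.56 and 0.51, edgeR adjusted p = 0.0227, 0.00796, 0.00515 and 0.00508), to 10.57 ± 7.001, 9.027 ± 3.716, 28.25 ± 16.31 and 16.16 ± 8.97 CPM. An arm led by CCGGACACGGACAGGA rose by 3.05 (adjusted p = 0.0385) and kept the call in 4 of the 12 fits only. A pair of arms led by GGGCTGGAGAGATGGCT, also of B2, rose by 3.19 and 3.17, and an arm led by CGTTAAAGGCTAGGC rose from 12.4 ± 15.3 to 106.7 ± 23.2 CPM (3.11, SE 0.60, adjusted p = 0.00796). An arm led by ATGATACTGTAAACGCTTTCTGATG fell from 111.0 ± 78.5 to 21.9 ± 7.8 CPM (−2.34, SE 0.47, adjusted p = 0.00977). Among annotated arms miR-3108-3p fell by 2.12, and its most frequent read, TTTTTTTTTTCGGCG, did not match its precursor exactly (chromosome 8, 108936860 to 108936938, in an intron of Zfhx3).

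**Figure D2:**
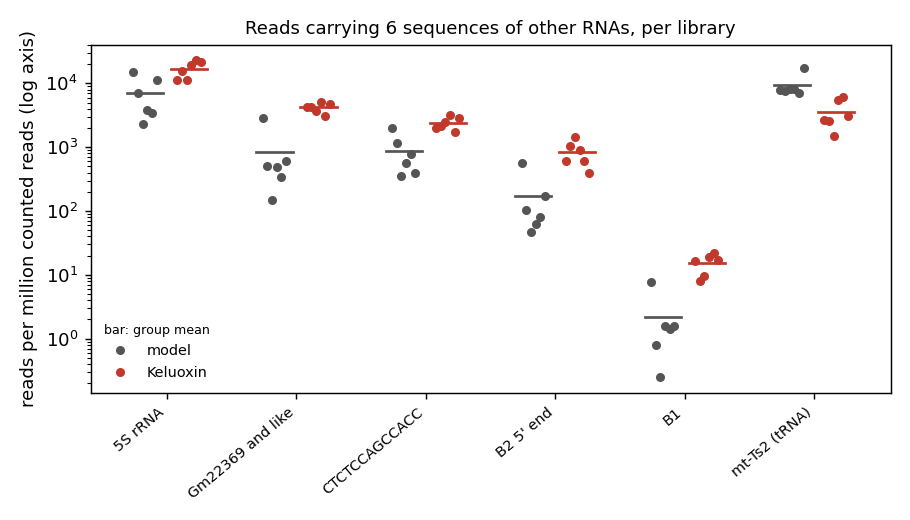
RPM (log axis) of reads that carry any of 6 short sequences, in each of 6 model and 6 Keluoxin libraries. The Gm22369-like sequence is shared by annotated miRNA genes. Points are libraries and short lines arithmetic group means. Gm22369-like reads lie between 3099 and 5046 in Keluoxin and above all model libraries, and mt-Ts2 reads lie below all model libraries.

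The libraries of the groups also differed in make-up. Reads that differ from their precursor took 40.7% ± 1.7 of the model reads and 48.1% ± 2.5 of the Keluoxin reads, higher in 6 of 6 Keluoxin libraries than in any model library (exact permutation test, p = 0.00217, adjusted over 7 measures 0.0152). The most abundant miRNA was taken in each library by itself and need not be the same one. In Keluoxin the mean of miR-183-5p, 138400 ± 39490 CPM, was above that of miR-182-5p, 120000 ± 28350. The most abundant miRNA of each library took 17.2% ± 0.65 of the model reads and 14.4% ± 2.6 of the Keluoxin reads. The 10 most abundant of each library took 65.2% ± 1.5 and 60.9% ± 3.4 (exact permutation test, adjusted p = 0.0303 each, lower in 4 of 6). These shares passed in only 5 and 6 of the 12 tests with 1 library left out, and not with reads on a single precursor (adjusted p = 0.0808 each). The number of arms with 10 reads or more, the mean read length and the share of the 5p arm did not pass (adjusted p = 0.535, 0.604 and 0.418, exact permutation tests). Most of the difference in mismatches lay at and near the last base. Reads ending in a changed C rose from 4.53% ± 0.83 to 7.80% ± 1.43, and those ending in a changed G from 3.98% ± 0.39 to 6.35% ± 1.64 (exact permutation tests, adjusted p = 0.0101 and 0.0114). A last base changed to A took 11.2% ± 0.62 and 10.1% ± 1.2, and one changed to T took 9.47% ± 0.84 and 8.56% ± 0.70 (adjusted p = 0.0808 each, exact permutation tests). Changes 1 or 2 bases before the last rose from 2.91% ± 0.70 to 5.88% ± 0.99 (exact permutation test, adjusted p = 0.00758). Inserted or deleted bases were rarer and rose from 0.668% ± 0.112 to 1.127% ± 0.148 of reads (exact permutation test, adjusted p = 0.00758). Those within 2 bases of the last rose from 0.575% ± 0.116 to 1.003% ± 0.130, and those further inside from 0.093% ± 0.020 to 0.124% ± 0.026 (exact permutation tests, adjusted p = 0.00433 and 0.0411).

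**Figure D3:**
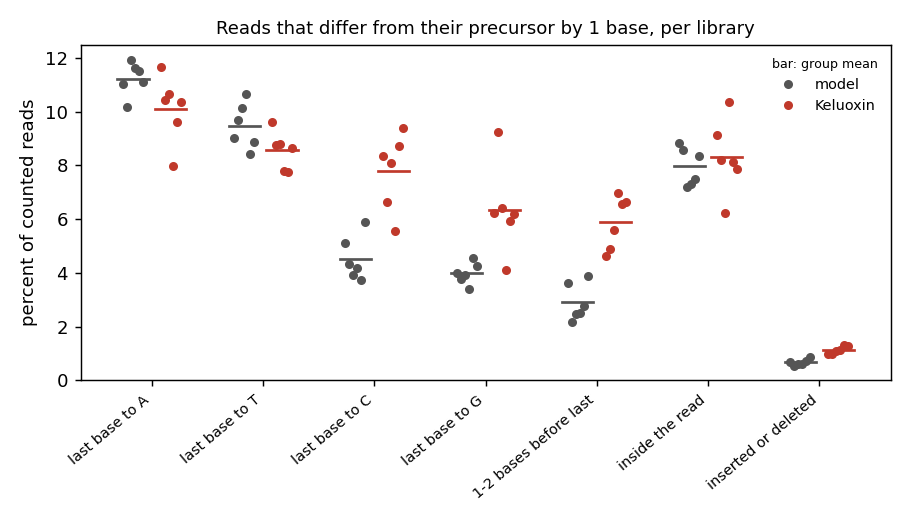
Percent of counted reads that differ from their precursor at the last base, in the 1 or 2 bases before it, further inside the read, or by an inserted or deleted base, in each of 6 model and 6 Keluoxin libraries; points are libraries and short lines group means. Changes of the last base to C lie at a mean of 4.53% in model and 7.80% in Keluoxin, and changes inside the read at 7.96% and 8.32%.

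The balance of the 5p and 3p arms shifted for 22 of 147 precursors (limma, adjusted p under 0.05), 10 toward the 5p and 12 toward the 3p arm. For miR-369 the log2 ratio of 5p to 3p reads fell from −2.01 ± 0.26 to −3.05 ± 0.18 (SD, n = 6, limma adjusted p = 0.00164). For miR-582 it rose from −2.27 ± 0.08 to −1.33 ± 0.28 (adjusted p = 0.00206). For miR-126a it rose from −3.28 ± 0.27 to −2.36 ± 0.21 (adjusted p = 0.00286), as the 3p arm fell and the 5p arm stood at 171.6 ± 37.1 and 208.1 ± 32.6 CPM. The smallest p was that of a predicted precursor, whose log2 ratio fell by 2.97. The count was 10 without model replicate 3, 4 or 6, 12 without model replicate 2 or 5, and 14 without Keluoxin replicate 1.

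The mean read length differed for 31 of 382 arms, 21 longer and 10 shorter in Keluoxin. With reads without a mismatch only 4 of 256 arms passed, and 3 of these were among the 31. miR-15b-5p was shorter, at 20.46 nt ± 0.05 against 20.76 ± 0.09 (limma adjusted p = 0.00304). The 3 smallest p were those of predicted arms, which changed by −0.82, 1.37 and −0.61 nt. The count was 74 without Keluoxin replicate 4, 14 and 15 without model replicates 5 and 3, 17 without Keluoxin replicate 3, and 18 without Keluoxin replicate 1 or 6.

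The 5′ start, which sets the seed, shifted for 14 of 382 arms, 5 more often and 9 less often in Keluoxin. Reads of miR-182-3p with another than the most frequent start took 58.7% ± 4.4 in model and 36.9% ± 8.3 in Keluoxin (limma adjusted p = 0.0161), and those of miR-690-3p 73.5% ± 15.3 and 35.4% ± 3.5 (adjusted p = 0.0161). A pair of predicted arms (adjusted p = 0.00469 and 0.0161) rose from 33.3% ± 6.3 to 62.2% ± 7.3 and from 35.8% ± 6.9 to 53.6% ± 2.5. Of miR-125b-5p reads, 3.14% ± 0.24 and 2.37% ± 0.19 had another start (adjusted p = 0.0481). The count was 23 without model replicate 1, 8 without model replicate 3 or 6 or Keluoxin replicate 4, 6 without model replicate 5 or Keluoxin replicate 1, and 5 without Keluoxin replicate 6.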

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

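All tests of explanations in this part were chosen after the results were seen. Of 174 groups of 6 libraries tested for a library far from the others, 18 had one, and 9 of the 18 were Keluoxin replicate 4. Independent and normally distributed values would give about 8.7. These values were not log-transformed, some arms are related and some were picked for their change. The 18 against 8.7 therefore measures no excess.

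Keluoxin replicate 4 held 9994 CPM of miR-184-3p (the other Keluoxin libraries held 69.95 to 179.2), 1693 of miR-1a-3p (247.5 to 383.1), 160.2 of miR-133a-3p (15.85 to 27.79), 18.8 of miR-133b-3p, 542.8 of miR-31-5p (13.06 to 28.41), 21.71 of miR-205-5p (0.815 to 7.65) and 40390 of miR-96-5p (53600 to 55500). Its mean read length was 21.136 nt and its share of 5p reads 74.189%, the lowest of the group. Of the 5 tested muscle arms, 4 had their highest level in this library, against 116 of 806 other arms (Fisher exact test, adjusted over 18 lists 0.0366). These include miR-1a-3p, miR-133a-3p and miR-133b-3p, listed above as outlying, and precursors of miR-1a and miR-133a are neighbours in the genome. The arms are thus not independent, and the p-value describes values already seen. miR-204-5p, abundant in pigment epithelium, stood at 7138 CPM, within the range of the model libraries. For miR-205-5p the model libraries ran up to 39.73 CPM.

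Model replicate 1 stood apart from the other model libraries in 4 arms that carry repeated sequences: miR-3473a-3p at 73.25 CPM (others up to 10.11), miR-3473f-3p at 69.47 (10.52), miR-1195-3p at 14.65 (3.43) and miR-3473e-5p at 10.16 (3.10). Keluoxin replicate 3 held 31.64 CPM of miR-3473e-5p. Model replicate 2 held 1078 CPM of miR-132-3p and 855 of miR-23b-3p, and model replicate 5 held 2.9 of miR-676-5p. Keluoxin replicate 5 had the fewest reads of its group, 1933375.

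The first pattern weighed was the larger share of reads with a changed last base in Keluoxin. Base-calling errors along the whole read would raise changes inside the read as well, but these stood at 1.045 times the model level, against 1.722 times for a last base changed to C. By arm, changes inside the read were higher in 69 of the 100 most abundant annotated arms, by a median of 0.26 percentage points, so a small rise is not excluded. Inserted or deleted bases rose as well, to 1.688 times, mostly within 2 bases of the last. Tailing with A or U after cutting would raise last-base changes to A or T, but these were higher in 27 of the 100 most abundant annotated arms only. Last-base changes to C or G were higher in 100 of those 100 arms, so a library-wide difference in preparation or sequencing may be the cause; the labels give no batch, and it cannot be told apart from the treatment.

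The second pattern was the excess of higher calls among predicted arms, 54 higher and 16 lower, where copies that share reads count as separate arms. Reads with mismatches placed on the wrong precursor as the whole cause would remove it in reads without a mismatch, where 85.11% of the calls were still higher. That fit tested only 164 of the 300 predicted arms, with 40 higher and 7 lower. In the median predicted arm 87.0% of reads had a mismatch, against 41.5% in the median annotated arm. The fit therefore leaves open where most reads of the predicted arms come from. More breakdown of all longer RNAs would not lower mitochondrial tRNA, whose share fell by 0.3365 percentage points (exact permutation test, adjusted p = 0.00722); breakdown of longer RNAs other than mt-Ts2 stays open, since the mitochondrial tRNA left without it rose by 0.0727 points without passing (p = 0.182). Repeated sequences and 5S ribosomal RNA, with their variants, make up 29 of the 54; among the other arms 60.98% of the calls were higher, but the sequences were chosen from the higher arms, so this share decides nothing and they stay open as the whole cause. A library-wide difference stays open as well, as does the treatment.

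The third was miR-451a-5p, high in 4 of 6 Keluoxin libraries. Blood of one composition in these libraries would bring miR-486a-5p in a fixed ratio: at the ratio of replicate 3, replicate 4 would hold 137.9 CPM and held 30.44, and replicates 5 and 6 would hold 231.48 and 69.98 and held 68.14 and 40.29. All 3 were further off than 2 SD of the model libraries. This band is narrow: replicates 1 and 2, with miR-451a-5p in the model range, held 26.7 and 47.19, also outside it around the model mean of 32.58. The ratio rests on replicate 3 alone and carries no error, so missing the band by itself decides little. Blood that differs in composition between mice, and a change in the retina itself, were not tested.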

How the results depend on the processing

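Most alternatives were fixed before the data were examined; fits with annotated precursors only, without model replicate 1 and Keluoxin replicate 4, and with the share of predicted precursors as a covariate were added afterwards, and the tests over splits of the libraries were chosen after the results were seen. The count of 140 arms stayed within 1.5 times of it under 11 of the alternatives fixed before. With DESeq2, which kept 1344 arms by its own filter, it was 236 (139 of them shared). With annotated precursors only it was 75 of 508 arms, and it was 228 without model replicate 1 and Keluoxin replicate 4 and 28 with the covariate; for these and the following values the cause was not tested. Leaving out each library gave 72 to 244. miR-6481-3p reversed to 0.8655 with reads of 18 to 26 nt.

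The list count of 1 was 0 with an estimated correlation, 0 with fry for one direction and 0 with annotated precursors only, and 0 to 1 with a library left out. Of the arm ratio, 22 calls became 13 with the replicate number as a block, and 10 to 27 with a library left out. Of the read length, 31 became 14 with 200 reads at least, 4 without mismatches, 87 without the pair, and 14 to 74 with a library left out. Of the 31, 13 lie on annotated arms. Fits of annotated precursors alone gave 9, and 2 when reads with a mismatch were also left out. The start shift, 14, became 9 with 200 reads, and 5 to 23 with a library left out. Of the 14, 5 lie on annotated arms, and a fit of annotated precursors alone gave 3. The composition count of 3 became 1 with reads on a single precursor, and 1 to 3 with a library left out.

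The shared replicate numbers do not pair the samples: same-number correlations ran from 0.0369 to 0.237, and 1 of 6 samples correlated best with its own number. With the number as a block, 137 arms passed (106 shared; miR-451a-5p, at 2.363, had adjusted p = 0.0865), 1 list, 13 arm ratios, 51 lengths, 2 start shifts and 0 composition measures, where the smallest p of 64 sign flips is 0.03125.

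Of 100 splits of the 12 libraries (of 462), only the real one gave as many arms (140, highest other 0). It was also the only one with as many arm ratios (22, highest other 1) and start shifts (14, highest other 1). As many lists came from 87 splits (1, highest other 7), so the list call does not stand out from other groupings. As many lengths came from 2 (31, highest other 63). The split with 63 points to a structure among the samples that may also lie behind the 31. All other splits mixed model and Keluoxin libraries, so any difference between the groups widened the spread within their sides and lowered their counts. The splits thus tie the arms, arm ratios and start shifts to the grouping of these samples. They cannot tell the treatment from a batch that goes with it. Of 1350 values for named arms under alternatives, 1167 kept their side of the threshold, 165 lost the call, 17 gained it and 1 reversed; of 324 for lists 5 lost it, of 105 for library measures 19, and of 137 for single arm, length and start results 2. With the library sizes and the spread between these samples, the simulated fit found few changes of 1.5-fold.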

Other observations

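The tests in this part were chosen after the data were seen, and cover 179 arms with at least 5000 reads over a position. Positions near the end of the read were left out, with an end gap of 4 nt. The frequent changes of the last base described above are therefore not covered. Among the positions searched, a single base of the read differed from the precursor in over 2% of reads at 12. Of these 12, 9 were A-to-G changes, the kind left in sequenced cDNA by adenosine-to-inosine editing. Positions are counted from 1 at the 5′ end of the read. The largest shares were A7G in miR-3099-3p, 56.1% of 5943 reads, and A6G in miR-376b-3p, 53.6% of 10686. A5G in miR-411-5p stood at 26.8%, A7G in miR-376b-5p at 20.2% and A5G in miR-379-5p at 10.2%. miR-378a-3p (A16G), miR-381-3p (A4G), miR-300-3p (A7G) and miR-132-5p (A1G) had 3.87%, 3.79%, 3.09% and 2.86%. Of these 9 changes, 6 lie in miRNAs of the Dlk1-Dio3 cluster (miR-376b, miR-411, miR-379, miR-381 and miR-300).

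Of these A-to-G shares 0 passed between the groups after adjustment over the 12 positions, and 2 had an unadjusted p under 0.05. miR-3099-3p stood at 58.8% ± 2.3 in model and 52.6% ± 3.8 in Keluoxin (n = 6 each, exact permutation test, p = 0.0108, adjusted 0.0649, lower in 5 of 6), and miR-379-5p at 10.8% ± 1.0 and 9.06% ± 1.32 (p = 0.0346, adjusted 0.139, exact permutation test). In both, the level of the arm fell as well.

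miR-127-3p, of the Dlk1-Dio3 cluster, was uneven in Keluoxin: replicates 3 and 6 held 1525 and 1232 CPM, and the other 4 held 299.3 to 594.8 against 288.7 to 434.7 in model (edgeR adjusted p = 0.0758). miR-122-5p was above the model range of 1.18 to 4.89 CPM in all Keluoxin libraries except replicate 4, with 41.2 and 25.49 in replicates 5 and 2; these were not the libraries with the most miR-451a-5p in every case, since replicate 4 held 358.7 of that and 2.38 of miR-122-5p.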
